A study of Homo sapiens with 9 samples.

How the data were processed

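Gene counts came from RNA-seq of 9 libraries of the H1 human embryonic stem cell line, 3 each in PXGL, N2B27 and N2B27 with 5 µM EPZ-6438 for 3 days. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a ribosomal RNA depletion kit; the molecule label names polyA RNA, and which of these holds was not settled. Strandedness is not given in the sources used here, so reads of overlapping genes and antisense partners, which are common in the HOX clusters, cannot be told apart. The authors deposited 1 table of expected counts, estimated counts that need not be whole, for 40332 gene symbols. Per the submitters' processing notes, Trim Galore, STAR 2.7.6a and DESeq2 were used with the hg38 genome; the step each tool served, the counting program and the annotation are not given in the sources used here. Between 7.13% and 8.09% of all values per library were not whole, as counts are when reads are divided between genes. These values include the many genes without a count. After rounding, 18150 to 18863 genes per library had a count, so the share among counted genes was higher. Genes with near-identical copies carry an uncertain split.

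Expected counts were rounded to whole numbers. Each column was matched to a library by its label, and groups were taken from the sample titles. Total counts were 14482105 to 18358530 per library, at which 3 counts correspond to 0.163 to 0.207 CPM; floors and counting intervals (95%) cover counting error only, and PCR duplicates are not removed from them. No replicate pair within a group differed by as little as sampling noise (chi-square per degree of freedom of 2.57 or more over genes with at least 20 counts in the pair), and all 9 libraries were kept as separate samples. The sources do not say whether replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical. The series text speaks of both triplicate samples and duplicate RNA-seq for this experiment, and the labels give 3 libraries per group.

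Genes were kept by edgeR's filterByExpr with the group, which left 15179 of 22640 genes with any count. All 9 libraries were fitted together in 1 model with a term for each group and a shared estimate of the spread. The fit used edgeR 4.0.16 (TMM scaling, robust quasi-likelihood fit, R 4.3.3). The 3 pairs of groups were compared with Benjamini-Hochberg adjusted p under 0.05 and no fold threshold. Before the data were examined, 27 gene lists were fixed: hypoblast, naive pluripotency, core pluripotency, primed and formative pluripotency, trophectoderm, amnion, mesendoderm and definitive endoderm, neuroectoderm, extraembryonic mesoderm, fibroblast, 8-cell-like, germ line, PRC2 subunits, HOX clusters, other PRC2-target developmental regulators, ERK-, WNT-, LIF-STAT3-, NODAL and TGF-beta and BMP-responsive genes, p53 targets, integrated stress response, hypoxia and glycolysis, cholesterol synthesis, cell cycle G2 and M, DNA methylation and demethylation, and mitochondrial-encoded genes. Some genes stand in more than 1 list. Members below the filter were not tested. Tested were 28 of 39 HOX genes, 44 of 85 other PRC2 targets, 22 of 34 hypoblast and 15 of 25 trophectoderm genes. So were 12 of 23 neuroectoderm and 8 of 16 extraembryonic mesoderm genes. The filter can keep a gene expressed in 1 group only. Genes counted only with the inhibitor can enter, and genes silent throughout do not. Shares that rose are therefore shares of tested members. Lists were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and an inter-gene correlation of 0.01, with adjustment over 81 tests, and again with an estimated correlation and with fry. A call lost with an estimated correlation is given with that adjusted p.

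The named genes were chosen by a rule fixed before the data were examined. It names EZH2, EED, SUZ12, GATA6, GATA4, SOX17, PDGFRA, KLF17, POU5F1, NANOG and SOX2 in each comparison, the 6 largest increases and 6 largest decreases with adjusted p under 0.05, non-overlapping ranges and a mean of at least 5 CPM in the higher group, and up to 3 called members with the smallest adjusted p of each list, or 6 for the hypoblast and naive lists. Some genes that the rule names are not reported here. Clone names, antisense and other non-coding names and pseudogenes were left out of the largest changes. A fold against a group with no counts was computed against 3 counts over the group, and a ratio to 1 to 3 counts is given with its counting interval. Coordinates and Ensembl identifiers came from GENCODE 29 on the same assembly, to which 40148 of 40332 symbols matched, and transcript length and GC content came from its transcripts.

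Recovery was tested on simulated data for the inhibitor against N2B27: in a step run on 14424 genes, 69.1% of genes changed by 1.5-fold and 84.4% of genes changed by 2-fold were recovered, and 9 calls were false. Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0's Wald test, a fit of only the 2 groups compared, a replicate block, edgeR's glmTreat with a 1.5-fold threshold, leaving out each library in turn, and for lists an estimated correlation and fry. Leaving out PXGL replicate 1 also for the comparison of the inhibitor with N2B27 and for the overlap of calls, and a scan of gene families, were added after seeing the data.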

Results

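RNA-seq libraries were measured from H1, an established human embryonic stem cell line, in 3 groups of 3 libraries. The first group was kept in PXGL, a medium that holds human pluripotent cells in a naive state with inhibitors of MEK, tankyrase and protein kinase C plus the cytokine LIF. The second group was in N2B27, the basal medium without these additions, and the third was in N2B27 with 5 µM EPZ-6438, an inhibitor of the catalytic activity of EZH2, for 3 days. EZH2 is the histone methyltransferase of Polycomb repressive complex 2 (PRC2), which deposits H3K27me3 at repressed developmental genes. The duration of culture in N2B27 without the inhibitor was not given in the sources used here. It may not match the 3 days of the inhibitor group, so differences between these 2 groups may include time out of PXGL. Total counts per library were 17499688 to 18358530 in PXGL, 14482105 to 15295208 in N2B27 and 14719626 to 16479602 in N2B27 with EPZ-6438. The first principal component held 63.0% of the variance and separated PXGL from the other groups. The second held 17.9% and separated the inhibitor group from N2B27. The biological coefficient of variation was 12.5% among the PXGL libraries, 4.83% in N2B27 and 5.70% with the inhibitor. PXGL replicate 1 stood apart from the other PXGL libraries, and ribosomal protein genes took 7.19% of its counts against 5.90% and 5.49% in replicates 2 and 3. Levels below are TMM-scaled CPM as mean ± SD with n = 3 per group. Adjusted p is from edgeR's quasi-likelihood test over 15179 genes unless another test is named.

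The study asked whether PRC2 acting through EZH2 represses primitive endoderm (hypoblast) fate, and the inhibitor against N2B27 is the comparison made for that question. Genes of the HOX clusters, which specify position along the body axis and are classical PRC2 targets, rose together with EPZ-6438. Of 28 tested HOX genes 24 rose, none fell and 4 did not pass (camera adjusted p = 9.57e-16, 0.00683 with an estimated correlation). The median log2 fold change was 3.27, or 3.26 with genes of no count in 1 group at their bound. Genes with few counts kept their fitted value. HOXD13 (chromosome 2, 176092891 to 176095938, hg38) went from 0.409 ± 0.234 to 23 ± 1.92 CPM, a 54.6-fold increase (log2 5.77, SE 0.26, adjusted p = 1.58e-10). HOXC13 rose 10.5-fold and HOXA10 rose 26.4-fold. Counting by strand was not stated, so reads of HOX genes and their antisense or overlapping neighbours cannot be told apart. Of 85 other developmental regulators known as PRC2 targets, 44 were tested. Of these 25 rose, 1 fell and 18 did not pass (median 1.04, camera adjusted p = 5.49e-09, 0.00683 with an estimated correlation). Among them FOXC1, a forkhead factor, rose 8.26-fold to 12.4 ± 2.15 CPM and DMBX1 rose 2.92-fold to 27 ± 1.21 CPM. Among HOX genes 24 rose when adjusted over the list alone, and among the other targets 29 rose and 2 fell.

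Hypoblast genes moved more unevenly. Of 34 members 22 were tested, of which 12 rose, 3 fell and 7 did not pass. Adjusted over the list alone 13 rose and 3 fell. The list's call (median log2 fold change 0.64, camera adjusted p = 0.00187) was lost with an estimated correlation (adjusted p = 0.0693 with an estimated correlation). GATA6, a transcription factor that marks the earliest primitive endoderm (chromosome 18, 22169443 to 22202528), rose 10.8-fold from 0.731 ± 0.269 to 7.97 ± 1.65 CPM (log2 3.43, SE 0.30, adjusted p = 3.34e-07). GATA4, a later factor of the same family (chromosome 8, 11676959 to 11760002), rose 1.62-fold from 14 ± 0.877 to 22.7 ± 0.608 CPM (adjusted p = 0.000224). HNF4A, a nuclear receptor of visceral endoderm, rose 2.53-fold to 21.0 ± 0.818 CPM, and BMP2 rose 15.7-fold to 4.08 ± 0.431 CPM. The basement membrane genes FN1, COL4A2 and LAMB1 rose 2.47-fold, 1.69-fold and 1.67-fold. PDGFRA, the receptor used to isolate primitive endoderm cells, was at 5.57 ± 1.24 CPM with the inhibitor and 5.74 ± 0.700 CPM without it (log2 -0.04, SE 0.20, adjusted p = 0.907). SOX17, an endoderm transcription factor, lay below the expression filter with 32 counts over the 3 inhibitor libraries and 1 count over the N2B27 libraries, a ratio of 30.3 with a counting interval of 5.05 to 1232.

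**Figure D1:**
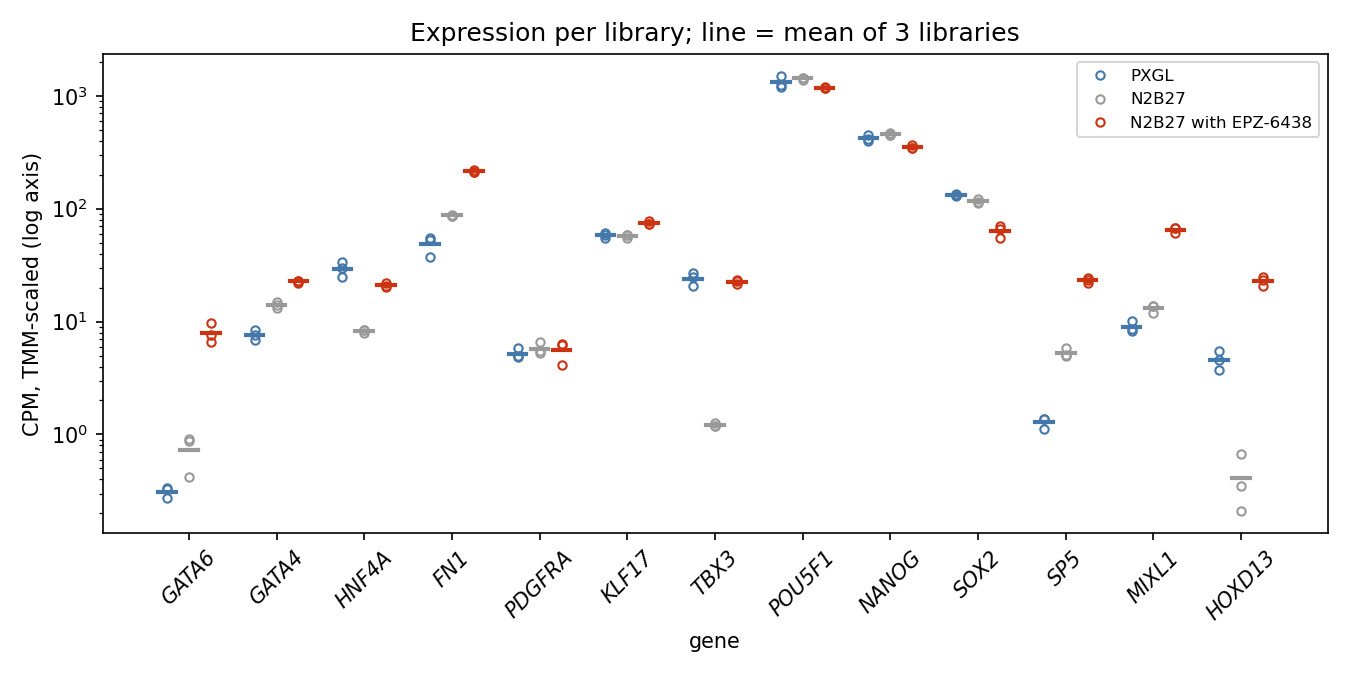
Expression of 13 genes in each of the 9 libraries, in TMM-scaled CPM on a log axis, with open circles for single libraries, lines for the means of 3 libraries, and colours for PXGL, N2B27 and N2B27 with EPZ-6438. GATA6 lies between 6.58 and 9.79 CPM in the inhibitor libraries and below 1 CPM in the others, while PDGFRA overlaps in all 3 groups.

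Core pluripotency genes fell with the inhibitor, but by small amounts. Of 14 tested members 11 fell, 1 rose and 2 did not pass (median log2 fold change -0.35, camera adjusted p = 4.21e-05, 0.0209 with an estimated correlation). SOX2 fell 1.83-fold from 116 ± 4.90 to 63.6 ± 7.50 CPM (adjusted p = 5.53e-07). NANOG fell 1.29-fold from 455 ± 10.8 to 353 ± 12.4 CPM (adjusted p = 0.000306) and POU5F1 fell 1.21-fold from 1426 ± 28.9 to 1178 ± 14.3 CPM (adjusted p = 0.0123). Genes of primed and formative pluripotency also fell on balance, 13 of 20 against 5 that rose and 2 that did not pass (median -0.65, adjusted p = 0.000363, 0.0299 with an estimated correlation). USP44, a deubiquitinase, fell 7.14-fold from 43.4 ± 0.647 to 6.11 ± 1.39 CPM. The de novo DNA methyltransferase DNMT3B fell 2.73-fold from 910.2 ± 12.0 to 333 ± 20.3 CPM and CD24 fell 2.24-fold. In the core list 12 genes fell and 1 rose when adjusted over the list alone, and in the primed list 13 fell and 7 rose. The POU5F1 call ended without N2B27 replicate 1 (adjusted p = 0.0587) or inhibitor replicate 2 (adjusted p = 0.0567). Naive pluripotency genes moved both ways, with 13 of 29 rising, 8 falling and 8 not passing, the same counts as adjusted over the list alone, and the list was not called (adjusted p = 0.187). KLF17, a naive-specific transcription factor, rose 1.29-fold from 57.7 ± 1.91 to 74.2 ± 2.55 CPM (adjusted p = 0.00114). TBX3 rose 18.5-fold from 1.22 ± 0.0321 to 22.6 ± 0.906 CPM and the DNA methylation cofactor DNMT3L rose 1.64-fold. The alkaline phosphatase genes ALPG and ALPP rose 2.54-fold and 2.30-fold, and their near-identical sequences leave the split of reads between them uncertain. FGF4 fell 2.05-fold from 101 ± 0.794 to 49.5 ± 4.19 CPM.

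Genes of other lineages rose beside the hypoblast list. In the mesendoderm list 10 of 15 rose, none fell and 5 did not pass, with 11 rising when adjusted over the list alone (median log2 fold change 1.54, camera adjusted p = 4.08e-06, 0.0165 with an estimated correlation). TBXT, the primitive streak factor brachyury (chromosome 6, 166157656 to 166168700), rose 11.3-fold from 5.81 ± 1.77 to 65.7 ± 2.74 CPM. MIXL1 rose 4.98-fold to 65.3 ± 3.81 CPM and the WNT target SP5 rose 4.41-fold to 23.3 ± 1.14 CPM. WNT-responsive genes rose in 7 of 11 cases with 4 not passing (adjusted p = 0.000133, 0.0311 with an estimated correlation). They included CDX1 by 4.44-fold, RNF43 by 2.33-fold and AXIN2 by 1.56-fold. In the neuroectoderm list 8 of 12 rose, 1 fell and 3 did not pass (adjusted p = 0.00105, 0.0417 with an estimated correlation). ZIC1, a zinc finger factor of neural development, rose 6.17-fold. Trophectoderm genes rose in 7 of 15 cases, fell in 1 and did not pass in 7 (adjusted p = 0.00775, lost at adjusted p = 0.0693 with an estimated correlation). GATA3 rose 3.26-fold to 6.68 ± 0.689 CPM. CDX2, a trophectoderm and hindgut factor, rose to 2.45 ± 0.455 CPM from 0.0457 ± 0.0396 CPM, a ratio of 52.9 with a counting interval of 14.3 to 443. Extraembryonic mesoderm genes rose in 5 of 8 cases with 3 not passing (adjusted p = 0.00129, lost at adjusted p = 0.0624 with an estimated correlation). HAND1 rose 4.06-fold to 18.9 ± 2.78 CPM. The amnion list, with 4 of 8 rising and 1 falling, was not called (adjusted p = 0.0942), but passed without any 1 of the N2B27 libraries or without inhibitor replicate 1 or 3, at adjusted p of 0.0243 to 0.0389. It also passed with no low-count filter (camera adjusted p = 0.0158). Adjusted over the list alone, 8 WNT-responsive, 8 neuroectoderm, 7 trophectoderm, 7 extraembryonic mesoderm and 4 amnion genes rose, and 1 fell in each of the neuroectoderm, trophectoderm and amnion lists.

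Genes that mark 8-cell-like cells, a state that resembles embryonic genome activation, rose in 15 of 16 cases, the same number as adjusted over the list alone, and 1 did not pass (median log2 fold change 2.25, camera adjusted p = 1.82e-12, 0.00651 with an estimated correlation). CCNA1, a germ cell cyclin, rose 3.16-fold from 63.4 ± 2.28 to 200.3 ± 11.3 CPM. SLC34A2 rose 4.21-fold to 44.2 ± 1.69 CPM and TRIM43 rose 3.29-fold to 44.0 ± 3.93 CPM. TRIM43 belongs to a family of near-identical copies, so its reads may be shared with them. Targets of p53 rose in 14 of 18 cases, with 1 falling and 3 not passing (adjusted p = 4.64e-08, 0.00683 with an estimated correlation). When adjusted over the list alone 16 rose and 1 fell. The cell cycle inhibitor CDKN1A rose 3.14-fold to 88.3 ± 2.83 CPM, GDF15 rose 3.44-fold and BTG2 rose 4.48-fold. Cholesterol synthesis genes fell in 12 of 22 cases with 10 not passing, or 16 adjusted over the list alone (adjusted p = 5.23e-07), a call lost at adjusted p = 0.145 with an estimated correlation. HMGCS1, which makes HMG-CoA, fell 1.37-fold. Mitochondrial-encoded genes fell in 4 of 13 cases, or 6 adjusted over the list alone (adjusted p = 0.00693, lost at adjusted p = 0.312 with an estimated correlation). They took 5.32% ± 0.25 of counts with the inhibitor against 5.80% ± 0.0367 without it. LIF-STAT3-responsive genes (6 rose and 1 fell of 11), BMP-responsive genes (5 rose of 10) and integrated stress response genes (7 rose and 1 fell of 17) were called higher at adjusted p = 0.0125, 0.0282 and 0.0456, and all were lost with an estimated correlation, at adjusted p = 0.0729, 0.106 and 0.293 with an estimated correlation. Of these, 6, 6 and 7 rose and 1, 0 and 2 fell when adjusted over the list alone. The integrated stress response call ended without N2B27 replicate 3, inhibitor replicate 1 or inhibitor replicate 2 (adjusted p = 0.0734, 0.0635 and 0.0562), and the BMP call ended with a stricter low-count filter (adjusted p = 0.0919). Examples were the cytokine receptor OSMR, up 2.53-fold, the BMP target ID2, up 5.47-fold, and the stress genes ATF3 and TRIB3, up 1.92-fold and 1.91-fold.

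The PRC2 subunit list was not called (adjusted p = 0.150), with 3 of 13 rising, 4 falling and 6 not passing. EZH2 itself (chromosome 7, 148807383 to 148884321) was at 82.5 ± 3.61 CPM with its inhibitor and 72.0 ± 2.86 CPM without it (log2 0.20, SE 0.07, adjusted p = 0.0415). EED rose 1.40-fold from 17.1 ± 1.21 to 23.9 ± 1.25 CPM (adjusted p = 0.00209) and SUZ12 fell 1.16-fold from 109 ± 1.44 to 94.3 ± 3.08 CPM (adjusted p = 0.0213). The EZH2 call ended when any 1 of the 6 libraries was left out, at adjusted p from 0.0534 without inhibitor replicate 1 to 0.165 without inhibitor replicate 2, and also with DESeq2 size factors (0.0517), DESeq2's own test (0.0541) or no low-count filter (0.123). The SUZ12 call ended without any 1 of the N2B27 libraries or without inhibitor replicate 2 or 3, at adjusted p of 0.0548 to 0.0885. The accessory subunits PHF19 and JARID2 fell 1.74-fold and 1.51-fold. NODAL and TGF-beta responsive genes (7 rose and 2 fell of 12, adjusted p = 0.0942), hypoxia and glycolysis genes (3 rose and 8 fell of 20, adjusted p = 0.103) and DNA methylation genes (3 rose and 5 fell of 9, adjusted p = 0.150) were not called either. In the latter list TET2 rose 5.61-fold. Germ line genes (3 rose and 2 fell of 15, adjusted p = 0.769), fibroblast genes (3 rose and 4 fell of 9, adjusted p = 0.844), ERK-responsive genes (3 rose and 5 fell of 19, adjusted p = 0.937) and G2 and M cell cycle genes (1 fell of 20, adjusted p = 0.490) were not called. Without PXGL replicate 1, a choice made after seeing the data, the NODAL and hypoxia lists passed at adjusted p = 0.0482 and 0.0355. Adjusted over the list alone, 4 PRC2 subunit, 7 NODAL, 3 hypoxia, 3 DNA methylation, 3 germ line, 3 fibroblast and 7 ERK-responsive genes rose, and 5, 2, 9, 5, 2, 4 and 6 fell, with 1 cell cycle gene falling. Median and mean log2 fold change differed in sign in the fibroblast list (-0.07 and 0.20, tested higher), the ERK-responsive list (-0.05 and 0.08, tested lower) and the DNA methylation list (-0.22 and 0.04, tested lower). Beyond HOXD13, HOXA10 and TBX3, the 6 largest increases held the carbonic anhydrase CA12 at 19.3-fold, the neurotrophin NTF3 at 14.6-fold and the kinase substrate MARCKS at 12.3-fold, which rose from 1.77 ± 0.627 to 21.9 ± 2.53 CPM. The 6 largest decreases were USP44, the cytochrome P450 gene CYP2B6 at 6.90-fold, CDH26 at 5.06-fold, MAMDC2 at 4.75-fold, LHFPL4 at 4.52-fold and FAM131B at 3.94-fold.

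Over all genes, 3752 of 15179 changed with EPZ-6438, 2149 higher and 1603 lower, and among those that changed by over 2-fold 811 were higher and 167 lower. Of 27 lists 17 were called, 13 higher and 4 lower, and 9 of these held with an estimated correlation. The count was 5641 when only the N2B27 and inhibitor libraries were fitted, 5770 when PXGL replicate 1 was left out, a choice made after seeing the data, and 724 when the test required a 1.5-fold change. Of the called genes 57.3% were higher in the main fit. That share was 51.8% with only these 2 groups fitted, 51.7% without PXGL replicate 1 and 85.1% with the 1.5-fold requirement.

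**Figure D2:**
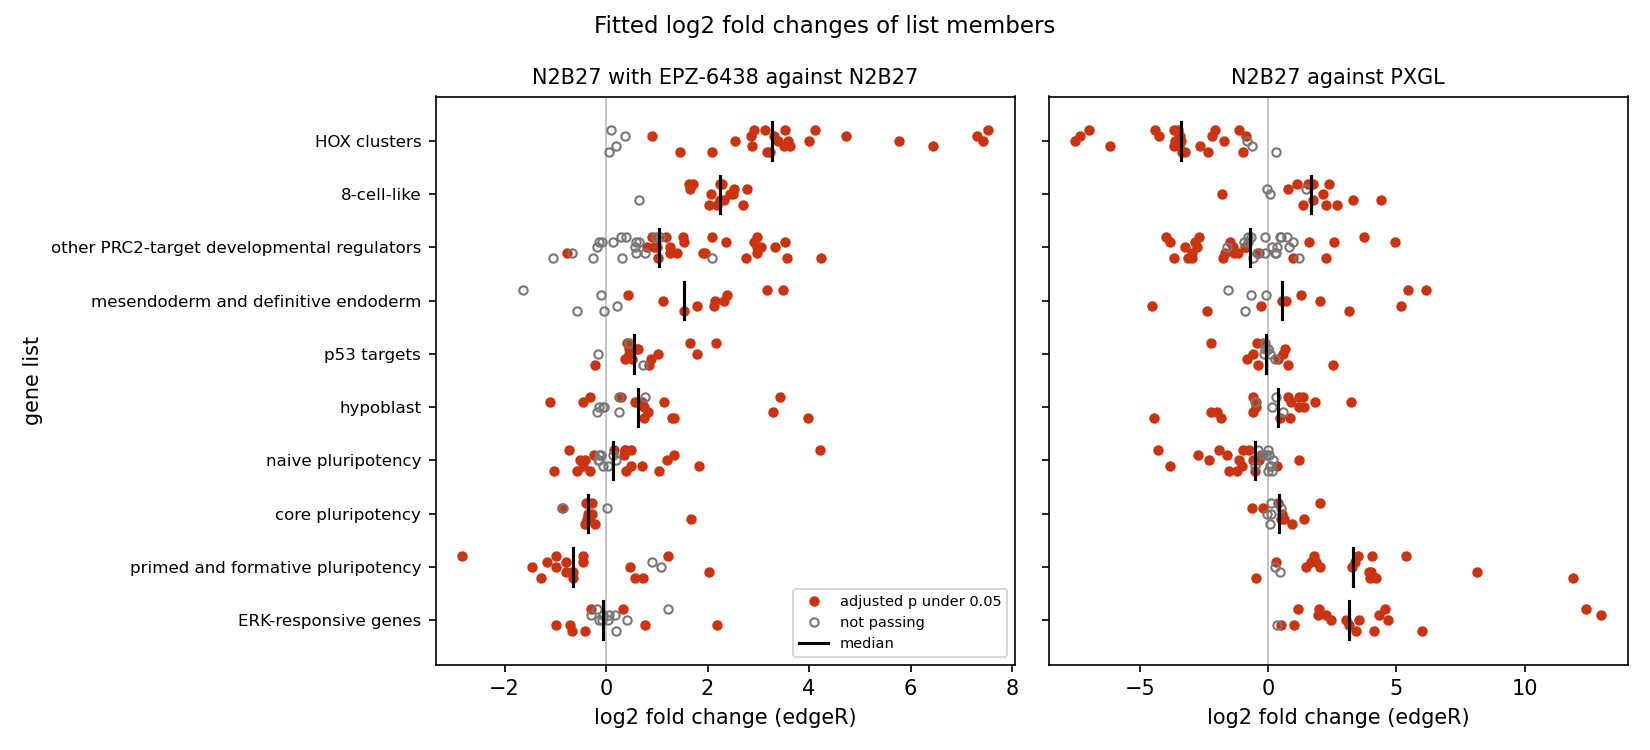
Fitted log2 fold changes of the tested members of 10 gene lists, with the inhibitor against N2B27 on the left and N2B27 against PXGL on the right; filled points passed at adjusted p under 0.05, open points did not, and black lines are medians. The HOX median is 3.27 on the left and -3.41 on the right, and fitted values of genes with few or no counts in 1 group depend on the prior count.

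N2B27 against PXGL compares the medium without and with these additions. ERK-responsive genes, which report signalling downstream of MEK, rose in 18 of 19 cases with 1 not passing, the same number as adjusted over the list alone (median log2 fold change 3.14, camera adjusted p = 3.78e-12, 0.00651 with an estimated correlation). DUSP4, a phosphatase that feeds back on ERK (chromosome 8, 29333064 to 29350668), had no count in PXGL and 62.7 ± 1.07 CPM in N2B27, at least 1138-fold higher against a floor of 3 counts over the group. SPRY4, another feedback inhibitor (chromosome 5, 142310427 to 142326455), went from 0.0183 ± 0.0317 to 139 ± 4.07 CPM (ratio 7553, counting interval 1355 to 298371), and PHLDA1 rose 17.5-fold to 118 ± 3.06 CPM. Primed and formative genes rose in 17 of 20 cases, with 1 falling and 2 not passing, also 17 and 1 when adjusted over the list alone (median 3.32, adjusted p = 2.49e-10, 0.00651 with an estimated correlation). FGF2 rose 15.1-fold from 22.5 ± 0.879 to 340.0 ± 2.97 CPM. The WNT antagonist SFRP2 rose 285-fold to 59.7 ± 0.296 CPM. The receptor phosphatase PTPRZ1 reached 97.2 ± 5.17 CPM from 0.0183 ± 0.0317 CPM (ratio 5295, counting interval 949.7 to 209171). Naive genes fell in 16 of 29 cases, rose in 2 and did not pass in 11, or fell in 17 and rose in 3 when adjusted over the list alone (median -0.50, adjusted p = 0.000294), a call lost at adjusted p = 0.141 with an estimated correlation. OLAH fell 14.2-fold from 78.8 ± 10 to 5.56 ± 0.396 CPM, TBX3 fell 19.7-fold, ALPG fell 6.70-fold, KLF4 fell 3.80-fold and KLF5 fell 3.04-fold. KLF17 was at 57.7 ± 1.91 CPM against 58.0 ± 2.95 CPM (log2 -0.01, SE 0.07, adjusted p = 0.923).

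HOX genes fell in 25 of 28 cases and 3 did not pass, with 25 also adjusted over the list alone (median log2 fold change -3.41, camera adjusted p = 3.24e-09, 0.0193 with an estimated correlation). HOXD13 fell 10.9-fold from 4.59 ± 0.880 to 0.409 ± 0.234 CPM. HOXB3 fell 4.49-fold from 13.2 ± 1.37 to 2.93 ± 0.305 CPM. The HOX median was -3.37 with genes of no count in 1 group at their bound. The other PRC2 targets fell in 19 of 44 cases, rose in 6 and did not pass in 19, also 19 and 6 adjusted over the list alone (adjusted p = 0.0485, lost at adjusted p = 0.119 with an estimated correlation). MEIS2 fell 14.1-fold and DMBX1 fell 7.16-fold, while GBX2 rose 13.5-fold. The 8-cell-like genes rose in 12 of 16 cases, fell in 1 and did not pass in 3 (adjusted p = 0.000345, 0.0339 with an estimated correlation). They included TRIM43 by 5.16-fold and SLC34A2 by 4.36-fold. Hypoblast genes split, with 10 of 22 rising and 8 falling, and the list was not called (adjusted p = 0.357). GATA6 was at 0.731 ± 0.269 CPM in N2B27 and 0.312 ± 0.0331 CPM in PXGL (adjusted p = 0.0264). That call ended without PXGL replicate 2, N2B27 replicate 1 or N2B27 replicate 3 (adjusted p = 0.0707, 0.0952 and 0.0881). GATA4 rose 1.84-fold (adjusted p = 1.22e-05), COL4A1 rose 3.57-fold, HNF4A fell 3.53-fold and BMP2 fell 21.5-fold. PDGFRA was at 5.74 ± 0.700 CPM against 5.21 ± 0.523 CPM (adjusted p = 0.569), and SOX17 had 1 count over the N2B27 libraries and 6 over the PXGL libraries.

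Core pluripotency genes rose in 7 of 14 cases and fell in 2 (adjusted p = 0.0106, lost at adjusted p = 0.0693 with an estimated correlation). Examples were L1TD1, up 4.11-fold, and LIN28A, up 1.93-fold. POU5F1 was at 1426 ± 28.9 CPM against 1319.7 ± 163 CPM (adjusted p = 0.217). NANOG was at 455 ± 10.8 CPM against 421 ± 23.7 CPM (adjusted p = 0.129) and SOX2 at 116 ± 4.90 CPM against 133 ± 2.43 CPM (adjusted p = 0.0483). Without PXGL replicate 1 POU5F1 and NANOG passed as higher in N2B27 (adjusted p = 1.80e-07 and 0.000470). The SOX2 call ended without PXGL replicate 2 or 3 or any 1 of the N2B27 libraries, at adjusted p of 0.0518 to 0.161, and with DESeq2 size factors (0.0713), DESeq2's own test (0.0976) or no low-count filter (0.0638). Cholesterol synthesis genes rose in 16 of 22 cases and fell in 1 (adjusted p = 0.000133, lost at adjusted p = 0.234 with an estimated correlation). HMGCS1 rose 2.29-fold. Integrated stress response genes rose in 12 of 17 cases (adjusted p = 0.000133, lost at adjusted p = 0.0904 with an estimated correlation). The serine synthesis enzyme PSAT1 was up 3.63-fold. NODAL and TGF-beta responsive genes rose in 8 of 12 cases and fell in 1 (adjusted p = 0.00149, lost at adjusted p = 0.0693 with an estimated correlation). LEFTY2 was up 2.51-fold. Fibroblast genes rose in 6 of 9 cases and fell in 1 (adjusted p = 0.00499, lost at adjusted p = 0.0624 with an estimated correlation). They were led by the surface glycoprotein THY1, up 188-fold to 118 ± 8.40 CPM, and the actin-binding TAGLN, up 30.2-fold. Cell cycle genes (10 of 20 higher and 2 lower) and BMP-responsive genes (6 of 10 higher) were called at adjusted p = 0.0371 and 0.0470 and lost at adjusted p = 0.175 and 0.136 with an estimated correlation. The cell cycle call ended without N2B27 replicate 3 (adjusted p = 0.0546), and the BMP call without PXGL replicate 3, N2B27 replicate 1 or N2B27 replicate 3 (adjusted p = 0.0649, 0.0618 and 0.0546) or with DESeq2 size factors (0.0514). Adjusted over the list alone, 7 core, 17 cholesterol, 13 stress response, 8 NODAL, 6 fibroblast, 11 cell cycle, 6 BMP-responsive, 12 8-cell-like and 10 hypoblast genes rose, and 2, 1, 1, 1, 1, 2, 0, 1 and 8 fell. Among PRC2 subunits JARID2 rose 4.32-fold and PHF19 rose 3.44-fold. EED fell 1.28-fold (adjusted p = 0.00751). SUZ12 fell 1.14-fold (adjusted p = 0.0156; 0.0567, 0.0524 and 0.0577 without PXGL replicate 3, N2B27 replicate 2 and N2B27 replicate 3, and 0.0518 with no low-count filter). EZH2 was at 72.0 ± 2.86 CPM against 78.3 ± 1.49 CPM (adjusted p = 0.133). Of the 6 largest increases NRK rose 446-fold to 208 ± 5.03 CPM, and THBS1 (ratio 406, counting interval 138 to 1970) and CSH1 (at least 93.8-fold higher) reached 22.3 ± 1.2 and 5.14 ± 1.03 CPM, with CSH1 sharing sequence with its growth hormone paralogs. The largest decreases included SLC12A3 at 87.1-fold, ATP6V1B1 at 70.8-fold, PRAME at 58.1-fold, FAM151A at 55.1-fold and the integrin ITGAM at 53.6-fold.

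Between N2B27 and PXGL 8505 genes changed, 4146 higher and 4359 lower, of which 1260 and 1512 changed by over 2-fold, and 2956 passed when a 1.5-fold change was required. Of 27 lists 13 were called, 10 higher and 3 lower, and 4 held with an estimated correlation. The call of the other PRC2 targets ended without any 1 of the PXGL libraries, at adjusted p of 0.0767, 0.108 and 0.0866 without replicates 1, 2 and 3, and with no low-count filter (0.181) or a stricter one (0.0582).

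N2B27 with EPZ-6438 against PXGL gives the net difference from the starting medium. HOX genes went both ways, with 6 of 28 higher, 5 lower and 17 not passing, also 6 and 5 adjusted over the list alone (median log2 fold change 0.01, camera adjusted p = 0.823). HOXD13 was 5.00-fold higher at 23 ± 1.92 CPM, while HOXB3 was 2.40-fold lower and HOXB2 2.06-fold lower. GATA6 was 24.9-fold higher (log2 4.64, SE 0.33, adjusted p = 4.72e-09) and GATA4 2.99-fold higher (adjusted p = 8.91e-09). The hypoblast list had 12 of 22 higher, 6 lower and 4 not passing, the same counts as adjusted over the list alone (adjusted p = 0.0282, lost at adjusted p = 0.152 with an estimated correlation). COL4A1 was 5.32-fold, COL4A2 4.42-fold and FN1 4.46-fold higher. PDGFRA was at 5.57 ± 1.24 CPM against 5.21 ± 0.523 CPM (adjusted p = 0.699), and SOX17 had 32 counts against 6. All 16 tested 8-cell-like genes were higher (median 3.98, adjusted p = 3.24e-09, 0.00683 with an estimated correlation), with SLC34A2 18.3-fold, TRIM43 16.9-fold and CCNA1 5.48-fold higher.

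ERK-responsive genes were higher in 18 of 19 cases and lower in 1 (adjusted p = 7.49e-12, 0.00651 with an estimated correlation). Primed genes were higher in 16 of 20 and lower in 1 (adjusted p = 7.06e-08, 0.00683 with an estimated correlation). Naive genes were lower in 18 of 29 cases and higher in 5 (adjusted p = 0.00129, lost at adjusted p = 0.175 with an estimated correlation). OLAH was 14.7-fold, FGF4 4.70-fold and KLF5 2.75-fold lower, and KLF17 was 1.28-fold higher (adjusted p = 0.000412). SOX2 was 2.09-fold lower (adjusted p = 8.49e-09), NANOG 1.19-fold lower (adjusted p = 0.00211) and POU5F1 was at 1178 ± 14.3 CPM against 1319.7 ± 163 CPM (adjusted p = 0.0720; 0.00816 without PXGL replicate 3 and 0.0370 with no low-count filter). Lists of p53 targets (14 of 18 higher, adjusted p = 0.000132), the integrated stress response (16 of 17, adjusted p = 3.18e-07), fibroblast genes (8 of 9, adjusted p = 0.000122), NODAL and TGF-beta responsive genes (10 of 12, adjusted p = 0.000207), BMP-responsive genes (9 of 10, adjusted p = 0.000294) and neuroectoderm genes (10 of 12, adjusted p = 0.00129) held with an estimated correlation, at adjusted p of 0.0485 or below. Mesendoderm, trophectoderm and WNT-responsive lists were called at adjusted p = 0.0125, 0.00537 and 0.0223 and lost at adjusted p = 0.0729, 0.0624 and 0.106 with an estimated correlation, and the WNT call also ended without inhibitor replicate 2 or 3 (0.0525 and 0.0549) or with a stricter low-count filter (0.0571). Adjusted over the list alone, 18 ERK-responsive, 16 primed, 5 naive, 15 p53, 17 stress response, 8 fibroblast, 10 NODAL, 9 BMP-responsive, 10 neuroectoderm, 10 mesendoderm, 11 trophectoderm, 8 WNT-responsive and 16 8-cell-like genes were higher. By the same adjustment 18 naive, 4 mesendoderm, 2 neuroectoderm, 2 trophectoderm, 2 WNT-responsive, 1 ERK-responsive and 1 primed gene were lower. TBXT was 809-fold higher at 65.7 ± 2.74 CPM. It had 1, 3 and 0 counts in PXGL replicates 1, 2 and 3, so the size of that fold is uncertain. TNC and ANKRD1, with no count in PXGL, were at least 128-fold and 243-fold higher against 3 counts over the group. The largest decreases included the ETS factor SPIC at 62.8-fold, PRAME at 39.3-fold and the kinase BTK at 25-fold, from 43.7 ± 4.37 to 1.76 ± 0.957 CPM. EZH2 was at 82.5 ± 3.61 CPM against 78.3 ± 1.49 CPM (adjusted p = 0.354), EED at 23.9 ± 1.25 CPM against 21.8 ± 1.26 CPM (adjusted p = 0.266), and SUZ12 was 1.32-fold lower (adjusted p = 4.09e-05). In all 8515 genes differed, 4259 higher and 4256 lower, and 14 of 27 lists were called, 13 higher and 1 lower, with 9 holding with an estimated correlation. With inhibitor against PXGL, 2928 genes passed when a 1.5-fold change was required.

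Genes that moved with the inhibitor were compared with those that had moved between PXGL and N2B27. Of the 2149 genes higher with EPZ-6438, 1030 were lower in N2B27 than in PXGL and 503 were higher. Of the 1603 genes lower with EPZ-6438, 787 were higher in N2B27 than in PXGL and 292 were lower. Independent calls would share 617 and 587 genes in the first pair and 438 and 460 in the second. Simulated unchanged groups against the same N2B27 libraries shared at most 1 call in 20 data sets, in which no comparison had over 3 calls, so this value sets no chance level for overlaps among real changes. Both comparisons use the same 3 N2B27 libraries, which are too few to split, so part of the excess in opposite directions may come from these shared libraries. Of the 1030 genes, 481 did not differ by the test between the inhibitor group and PXGL, 438 were still below PXGL and 111 were above it. Of the 787 genes, 395 were still above PXGL, 354 did not differ by the test and 38 were below it. Without PXGL replicate 1 the shared counts were 1422, 727, 1461 and 603, in the same order, a choice made after seeing the data.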

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

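Leaving out PXGL replicate 1 for the inhibitor against N2B27 and for the overlap of calls was chosen after seeing the data; the other alternatives were fixed before the data were examined. For the inhibitor against N2B27, the count of 3752 genes became 5641 when only these 2 groups were fitted, which leaves the wider PXGL spread out of the shared estimate, and 724 with a 1.5-fold threshold in glmTreat, which asks for a larger change by construction. Leaving out 1 library gave 2762 to 5770 genes, the highest without PXGL replicate 1. N2B27 against PXGL gave 2956 genes with the 1.5-fold threshold and 7663 to 9506 without single libraries, and the inhibitor against PXGL gave 2928 and 7599 to 9452. The 44 list calls of 81 became 22 with an estimated correlation, 74 with fry, which does not compare a list with other genes, and 41 to 46 without single libraries. The hypoblast call with the inhibitor was lost with an estimated correlation (adjusted p = 0.0693), and its adjusted p was 8.90e-05 to 0.00281 over the alternatives that kept camera's preset correlation, single libraries left out included. The naive list passed only with fry (adjusted p = 0.000108), against 0.164 to 0.278 over the same alternatives and 0.531 with an estimated correlation. The HOX list (3.42e-22 to 1.30e-10) and the other PRC2 targets (2.04e-09 to 4.82e-07) passed under all of these and with an estimated correlation and fry. The PRC2 subunit list, not called by camera, went the other way with fry in N2B27 against PXGL (adjusted p = 0.000177) and in the inhibitor against PXGL (adjusted p = 0.0226), and the cause was not tested. Without PXGL replicate 1 the calls shared by N2B27 against PXGL and the inhibitor against N2B27 were 603 lower in both and 1461 higher and then lower, from 292 and 787; that fit also called more genes in all, and which genes are shared was not compared. Same-numbered libraries deviated with correlations of -0.0256 to 0.0369, and 4 of 9 libraries correlated best with their own number, so the numbers were not taken to pair the samples. A replicate block gave 3696, 8507 and 8489 genes and 43 list calls, and it ended the calls of EZH2 with the inhibitor (adjusted p = 0.0574) and of the BMP-responsive list in N2B27 against PXGL (adjusted p = 0.0641). DESeq2 size factors moved the median log2 fold change by -0.01, 0.02 and 0.01 in the 3 comparisons. The 1.5-fold threshold ended the calls of 31 of 99, 16 of 106 and 11 of 102 tested named genes with the inhibitor against N2B27, in N2B27 against PXGL and with the inhibitor against PXGL. Depth limits genes near the floor of 3 counts, such as SOX17, whose counts of 32, 1 and 6 in the inhibitor, N2B27 and PXGL groups leave wide intervals.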

Other observations

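The scan of gene families and all tests of the HOX, PRC2-target and 8-cell-like patterns were chosen only after those results were seen; the tests of PXGL replicate 1 and of the splits were fixed before their results were seen. Families were formed from the stem of the gene symbol, with at least 8 tested members, which gave 287 stems and 861 tests over the 3 comparisons, tested with camera. The PRAMEF family, paralogs of PRAME that lie in many copies, rose with the inhibitor in 16 of 18 tested members (median log2 fold change 2.16, adjusted p = 2.18e-06, lost at adjusted p = 0.862 with an estimated correlation). It also rose in N2B27 against PXGL, in 13 of 18 (median 2.24, adjusted p = 0.00258, lost at adjusted p = 0.949 with an estimated correlation), and the inhibitor group stood above PXGL by a median of 4.23 (adjusted p = 2.18e-06, lost at adjusted p = 0.862 with an estimated correlation). These copies are near-identical, so the count of members that moved is uncertain.

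None of the 16 family calls held with an estimated correlation. Collagen genes rose with the inhibitor in 17 of 34 cases and fell in 3 (median log2 fold change 0.73, camera adjusted p = 0.000458, lost at adjusted p = 0.949 with an estimated correlation). Genes with the KLF stem rose in 9 of 16 and fell in 1 (adjusted p = 0.00304, lost at adjusted p = 0.862 with an estimated correlation). Genes with the BMP stem rose in 4 of 8 cases (adjusted p = 0.00745) and genes with the WNT stem in 5 of 12 (adjusted p = 0.0407), both lost at adjusted p = 0.949 with an estimated correlation. The UTP genes, most of which act in ribosome assembly, rose in N2B27 against PXGL in 10 of 11 cases by a median of 0.42 (adjusted p = 0.0212, lost at adjusted p = 0.949 with an estimated correlation).

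HOX and other PRC2-target genes were higher with EPZ-6438 than in N2B27. Against background reads as the cause, the highest inhibitor library over the lowest N2B27 library was 1.15 in summed CPM of olfactory receptor genes, which these cells should not express. Against depth, summed HOX counts thinned to the smallest library total were 2106 ± 136 with the inhibitor and 587 ± 61.0 in N2B27 (SD, n = 3), a ratio of 3.59. Random lists were matched on mean expression over all 9 libraries. The HOX median lay at percentile 100 of 10000 such lists, whose highest median was 0.86. This argues against a general rise of genes of low mean expression. The lists were not matched on the N2B27 level, so a general rise of genes low in N2B27 stays open. Inhibition of EZH2, which the design varied, stays open: the median of the other PRC2 targets also lay at percentile 100 (highest random median 0.79), but that list is part of the pattern, so its rise decides nothing. The time that the N2B27 group spent without PXGL is not known, so a difference in that time also stays open.

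The 8-cell-like genes were also higher with the inhibitor. Reads shared between near-identical copies would leave members with whole counts in all libraries (equal to the rounded value, with no tolerance) unmoved, but the 9 such members had a median log2 fold change of 2.24 and 8 of them were called higher, against a median of 2.29 in the other 7. A general rise of genes of low mean expression over all 9 libraries would put the list within random lists matched on that mean. Its median lay at percentile 100, above the highest random median of 1.11. These lists too were not matched on the N2B27 level, so a general rise of genes low in N2B27 stays open. An effect of EZH2 inhibition on these genes may be direct or indirect, and no biological explanation was tested.

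PXGL replicate 1 stood apart from replicates 2 and 3, with root mean square log2 differences of 0.454 and 0.477 against 0.370 between the others. Its deviation correlated with transcript length across 15135 genes, with a Spearman rho of -0.449, against -0.166 for the difference of replicates 2 and 3, so a length-related difference such as RNA fragmentation or library preparation may contribute. Against GC content as the cause, its rho was 0.0544. Genes are not independent replicates, and no biological explanation was tested. Across genes, the fold changes of the inhibitor against N2B27, N2B27 against PXGL and the inhibitor against PXGL correlated with transcript length at rho of 0.0928, 0.0486 and 0.103 and with GC content at rho of -0.0783, -0.174 and -0.218.

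Of the 10 splits of the 6 libraries in each comparison, 1, the real one, gave as many called genes. Every split, the real one included, was fitted with all 9 libraries, the 3 of the remaining group keeping their label. The real splits gave 3752, 8505 and 8515 genes for the inhibitor against N2B27, N2B27 against PXGL and the inhibitor against PXGL, and the highest of the other splits gave 0 in each. Every other split mixes libraries of both groups, so the difference between the groups enters its spread and holds calls down. The 0 therefore sets no chance level. The 10 splits are also too few for a share under 0.05.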
